A study of Bos taurus with 23 samples.

How the data were processed

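Poly(A)+ RNA of bovine oocytes and embryos was isolated with oligo-dT beads, converted to biotin-labelled cRNA by in vitro transcription and hybridised to bovine GeneChip arrays. In vivo oocytes came from the preovulatory follicles of 9 animals on day 0. Embryos came from animals inseminated with semen of a single bull; the zygote to 8-cell stages were flushed from the oviducts of 24 cows on days 1 to 4, and morulae and blastocysts from the uterus of 7 animals on days 7 to 8. Embryos were pooled by 10, and blastocysts by 5. The labels give no pool size for oocytes and no conditions of the in vitro culture.

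The deposited values are GCRMA expression values in log2 units, made by the authors with background correction, quantile normalization across arrays and summary per probe set (GCRMA 2.0.0 according to the submitters' processing notes). The scale was checked on the values, whose medians ran from 3.28 to 3.60 on the 23 arrays. The scanner files were not used, and no value was transformed again. The table holds 24128 probe sets, of which 112 are controls that were left out of all tests. Of the other 24016 probe sets, 13292 carry 1 gene symbol, 86 carry several and 10638 carry none, and together they name 9162 genes. Symbols are those of the platform's annotation, and a comparison with a RefSeq table changed 0 of them. That table gives no genome coordinates, so no positions are reported.

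A probe set was tested when its value exceeded 4 on at least 2 arrays, which kept 14571 probe sets and 7074 genes. A value of 4 was taken as the level below which signal is not told from background. Where any array of the lower group lay below 4, the arrays of that group were set to the higher of 4 and their own value. The fold of the higher group's measured mean over their mean is then given as at least that size. Groups were those of the labels. The labels do not say that numbers of replicates pair samples across groups, so the main fit used no pairing. Deviations from group means correlated between -0.377 and 0.491 in 21 pairs with the same number, and 5 of these were above 0.1. Deviations within a group cancel out, so these values are not independent and do not settle whether the numbers pair samples.

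Comparisons were made with limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes with a trend), with a mean for each of the 8 groups and a shared spread from all 23 arrays, leaving 15 residual degrees of freedom. The tests are two-sided. Their p values were adjusted by the Benjamini-Hochberg method within each comparison, and an adjusted p under 0.05 is called passed. Where leaving out an array left a group with 1 array, that array was assumed to vary like the other groups. The 8 comparisons were in vitro against in vivo oocytes, the 6 consecutive in vivo steps and the in vivo oocyte against the blastocyst. An F test over the 6 steps found probe sets with any change, and each of those whose stage means spanned at least 1 was assigned to its step of largest change. Tests read the spread between arrays of pools, so they do not describe variation between single embryos, and their precision is limited by the number of arrays. The labels do not say whether pools share donors, so the p values do not measure the spread between cows. From oocyte to zygote, 8-cell to morula and oocyte to blastocyst, the donor set, collection site and day change together with the stage. Their effects cannot be told apart from those of stage.

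There were 30 gene lists, 26 for processes of the oocyte and embryo and 4 for markers of other cell types (cumulus and granulosa cells, oviduct and uterine epithelium, blood and leukocytes, sperm and testis). A list was tested when at least 5 members were measured, each gene by its probe set with the highest mean. Marker genes above 4 on a single array were not kept by the filter. The tests of the marker lists leave such genes out, so they do not settle whether a single array carried RNA of other cells. Lists were tested with camera (limma) at a preset correlation of 0.01, which compares a list with all other genes, and the p values were adjusted over the 30 lists of a comparison. None of the 60 list calls held with an estimated correlation. The genes named are members of these lists and, for each comparison, the 8 with the largest rise and the 8 with the largest fall that passed, had non-overlapping arrays, a probe set with 1 symbol and no provisional name. Not every gene that this rule selects is discussed. The tests, the lists, the rule for named genes and the alternatives were chosen before the data were examined, with exceptions added after the data were seen. Some of these are marked where they appear: the naming of ZFP36L1, a count of stage peaks over every array and tests of flagged results. The other is leaving out arrays that carried markers of other cell types. That leaving out was done with 4 arrays (in vivo oocyte 2, 2-cell 1, 4-cell 1 and blastocyst 1) and, for the counts of probe sets, also with 6 (those 4, in vitro oocyte 3 and 8-cell 3). Arrays that were kept carried such markers too, among them in vivo oocyte 1 (CD44, CD3E and CD52), 8-cell 1 and 4 (OVGP1, HOXA10 and LUM) and morula 1 (ALAS2). HSD3B1 and KRT8 of the cumulus list also stood out on morula 1. Both lay above 4 on every blastocyst array, so they do not tell other cells from embryo cells there.

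The alternatives were no filter, a filter at 6, quantile normalization, centring on 9 probe sets of hybridisation spike-in controls, centring on array medians, eBayes without a trend or with the robust option, the replicate number as a block, a fit of the compared groups alone, an added 2-fold threshold, genes in place of probe sets, and each array left out in turn. Spike-in controls of this kind are added after RNA isolation and do not track RNA per embryo. The deposited values were already quantile normalized, so repeating that step is a weak check. The fit was tested on simulated data with 100 probe sets changed by 1 and 100 changed by 2 on the log2 scale. Between 1% and 10% of the former and between 18% and 67% of the latter were recovered, and in each comparison at most 7.84% of the calls were false. Camera found 2 of 2 shifted lists and 0 of 20 lists without a shift. The simulated noise was independent between probe sets, so these runs do not show how the tests behave where genes vary together. Few probe sets were changed in them, and the adjustment is less strict where many pass. The shares recovered thus do not describe the comparisons in which most probe sets passed. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.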

Results

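Levels of poly(A)+ messenger RNA were measured in bovine oocytes and in preimplantation embryos collected from cows, on 23 bovine GeneChip arrays. A change in such a level can come from the amount of a transcript or from its poly(A) tail, and these were not told apart. Quantile normalization gives all arrays much the same distribution, so rises, falls and folds are relative to the other transcripts on the arrays. They do not give amounts per embryo, and the balance of rises and falls does not show whether total mRNA changed. The arrays formed 8 groups. There were 3 arrays of in vitro oocytes, 3 of in vivo oocytes, 3 of zygotes, 2 of 2-cell embryos, 2 of 4-cell embryos, 4 of 8-cell embryos (described elsewhere in the series as 8- to 16-cell), 3 of morulae and 3 of blastocysts. Each embryo array held RNA from a pool of 10 embryos, or of 5 blastocysts. The labels call the arrays of a group biological replicates. Between 43.3% and 47.0% of the probe sets on each array lay above a log2 value of 4, and the array medians ran from 3.28 to 3.60. Group values below are means of log2 values ± SD over these numbers of arrays, and every adjusted p for a gene comes from limma.

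**Figure D1:**
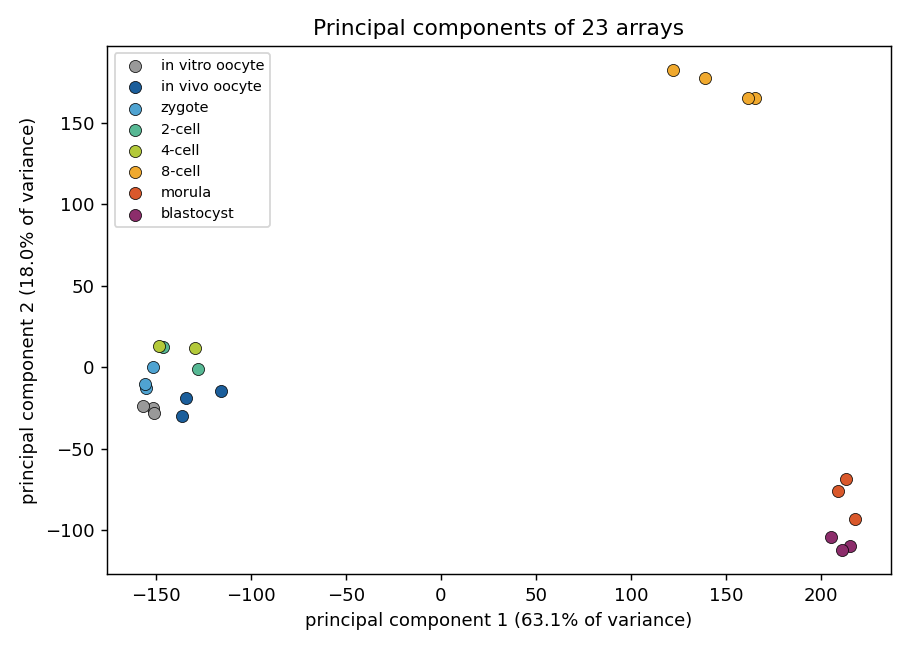
Each point is an array, placed by the first 2 principal components of the log2 values, with the share of variance on each axis (63.1% and 18.0%) and the groups in colour. The oocyte, zygote, 2-cell and 4-cell arrays lie together at the left, the 8-cell arrays lie at the top right and the morulae and blastocysts at the bottom right.

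The arrays from the oocyte to the 4-cell stage resembled each other closely, and the break came between the 4-cell and the 8-cell stage. Pearson correlations across probe sets between 4-cell and 8-cell arrays ran from 0.565 to 0.653, and those between 8-cell arrays and morulae from 0.696 to 0.769. Within groups they ran from 0.988 to 0.990 in the in vitro oocytes, 0.914 to 0.978 in the in vivo oocytes, 0.899 to 0.981 in the 8-cell embryos and 0.951 to 0.975 in the blastocysts. In vivo oocyte array 2 was nearer to the in vitro oocytes (0.967 to 0.972) than to in vivo oocyte arrays 1 and 3 (0.914 and 0.950). Probe sets are not independent replicates, so these values describe likeness and test nothing.

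**Figure D2:**
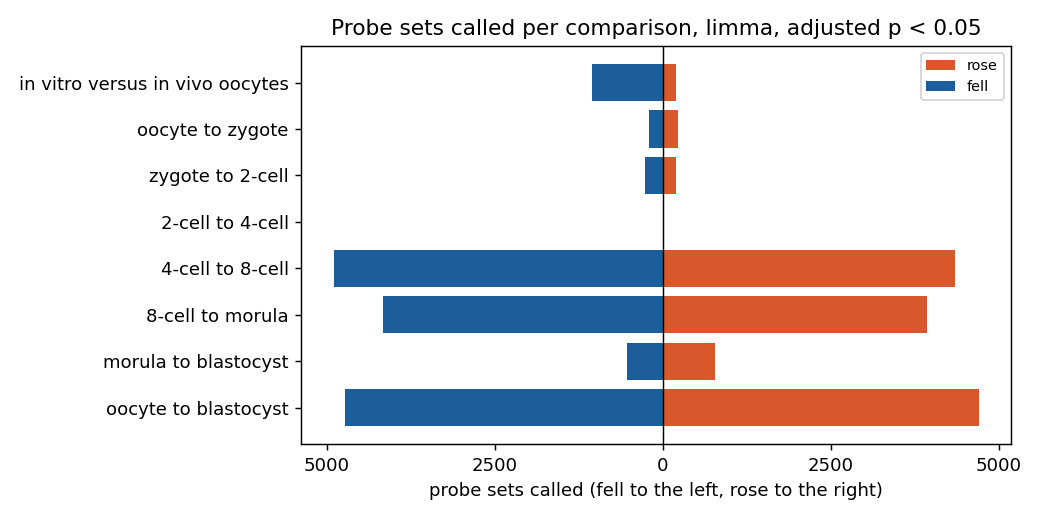
Bars give the number of probe sets that passed the limma test (adjusted p under 0.05) in each comparison, with those that fell to the left of 0 and those that rose to the right. The bars reach 4896 fallen and 4340 risen probe sets from the 4-cell to the 8-cell stage, against 1 and 1 from the 2-cell to the 4-cell stage.

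The first comparison asked how oocytes cultured in vitro differ from oocytes taken from preovulatory follicles. The labels do not give the point of maturation of either, nor whether or how long the former were matured in culture. Genes lower in vitro included members of the lists of oxidative phosphorylation (37 of 72), ribosomal proteins (20 of 62), translation factors (14 of 33) and the proteasome (10 of 26). SDHB, a subunit of respiratory complex II, stood at 4.51 ± 0.92 in vitro and 8.72 ± 0.49 in vivo, at least 17.4-fold lower (adjusted p = 9.07e-06). UQCR10 of complex III was 18.6-fold lower (adjusted p = 2.32e-06). GPX4, the enzyme that reduces lipid peroxides in membranes, was 24.2-fold lower at 6.82 ± 0.28 against 11.42 ± 1.23 (adjusted p = 4.01e-06). TKT, transketolase of the pentose phosphate pathway, was at least 27.9-fold lower (adjusted p = 2.32e-06). Of 72 measured genes of oxidative phosphorylation, 37 fell and none rose, 35 did not pass, and 44 passed when adjusted over the list alone. The median change of that list was -1.25 (camera adjusted p = 3e-16; adjusted p = 0.161 with an estimated correlation).

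Of 62 cytosolic ribosomal protein genes, 20 were lower in vitro and none higher, 25 passed adjusted over the list alone, and the median change was -0.57 (camera adjusted p = 1.6e-07; adjusted p = 0.334 with an estimated correlation). RPS6 stood at 10.13 ± 0.39 in vitro and 12.88 ± 0.54 in vivo, 6.72-fold lower (adjusted p = 4.96e-05). RPL7 was 5.57-fold lower (adjusted p = 4.01e-06). Among 33 translation factors 14 fell and 16 passed adjusted over the list alone (camera adjusted p = 0.000469; adjusted p = 0.161 with an estimated correlation), with EIF3D 13.0-fold lower (adjusted p = 5.19e-05). Among 29 genes of ribosome biogenesis 11 fell and 15 passed adjusted over the list alone (camera adjusted p = 0.000491; adjusted p = 0.334 with an estimated correlation). NHP2, a protein of the particles that modify ribosomal RNA, was lower by -4.02 on the log2 scale (adjusted p = 0.000245). Of 26 proteasome genes 10 fell and 13 passed adjusted over the list alone (camera adjusted p = 0.000469; adjusted p = 0.334 with an estimated correlation). PSMC1, an ATPase of its cap, was 6.82-fold lower (adjusted p = 0.000931).

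Among 25 genes of glycolysis and pyruvate metabolism 9 fell and 1 rose, and 15 passed adjusted over the list alone (camera adjusted p = 0.00124; adjusted p = 0.334 with an estimated correlation). Without 4 arrays that carried markers of other cell types the camera adjusted p of this list was 0.0865. ENO1, the enolase of glycolysis, was 16.7-fold lower in vitro (7.11 ± 0.70 against 11.17 ± 1.84, adjusted p = 0.000909), and LDHB, a lactate dehydrogenase subunit, was 15.3-fold lower (adjusted p = 3.12e-05). PDK4, a kinase that restrains pyruvate dehydrogenase, was the list's gene that rose, by at least 2.69-fold (adjusted p = 0.00668). Of 28 heat shock and chaperone genes 7 fell, with 10 adjusted over the list alone (camera adjusted p = 0.0162; adjusted p = 0.464 with an estimated correlation, and 0.126 with the mean of a gene's probe sets). DNAJB1, a co-chaperone of HSP70, was at least 21.2-fold lower (adjusted p = 2.21e-05). Higher in vitro were BMP4, a signalling ligand, by 6.54-fold (7.43 ± 0.28 against 4.72 ± 0.28, adjusted p = 0.000961), and MARS2, the mitochondrial methionyl-tRNA synthetase, by 5.70-fold (adjusted p = 0.00602). None of 12 oocyte-specific genes passed in either direction.

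In all, 1245 of 14571 probe sets passed, 197 higher and 1048 lower in vitro, in 880 genes of which 51 were higher and 829 lower. Camera called 9 of the 30 lists, 2 of them upward. The 9 pluripotency genes (camera adjusted p = 0.0316; 0.185 with an estimated correlation and 0.0568 without 4 arrays that carried markers) held 1 gene that passed, and the 23 adhesion genes (camera adjusted p = 0.0162; 0.161 with an estimated correlation) held none. In vivo oocyte array 2 carried 10 of 34 cumulus and granulosa cell genes at levels over 4 and over 2 (log2) above the other arrays of its group, among them HSD17B1 at 11.03 and INHA at 10.95. In vitro oocyte array 3 carried 4 of those genes, with TIMP1 at 8.84. In vivo oocyte array 1 carried CD44 of the same list at 5.19 and 2 of 22 blood and leukocyte genes, CD52 at 8.47 and CD3E at 5.13. As lists, cumulus and granulosa markers (0 of 25 passed, camera adjusted p = 0.352), oviduct and uterine markers (1 of 10, SERPINA14, at least 11.1-fold higher, adjusted p = 0.00415) and blood markers (0 of 8) gave no call, and 2 of 5 sperm and testis transcripts fell without a call for the list (camera adjusted p = 0.415). HSD17B1 and FST, above 4 on in vivo oocyte array 2 alone, were not kept by the filter and so were not among the 25 cumulus and granulosa genes tested. Leaving out in vivo oocyte array 2 raised the count to 2439, leaving out 6 arrays that carried markers raised it to 2066, and leaving out in vivo oocyte array 1 or 3 or in vitro oocyte array 1 or 2 lowered it to 508, 799, 732 and 770. With a spread taken from these 6 arrays alone 4 probe sets passed (limma; 3051 at an unadjusted p under 0.05), and with arrays centred on spike-in controls 686 passed, 44 higher and 642 lower.

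The steps between consecutive stages asked when levels of poly(A)+ RNA rise and fall relative to the other transcripts on the arrays. From the in vivo oocyte to the zygote, mRNAs of 32 of 62 ribosomal proteins and of 20 of 72 proteins of oxidative phosphorylation fell. RPL18 went from 13.29 ± 0.42 to 10.28 ± 0.87, 8.10-fold lower (adjusted p = 0.000981), RPL12 fell 12.0-fold (adjusted p = 0.00132) and RPL26 5.74-fold (adjusted p = 6.68e-05). Of 62 ribosomal protein genes 32 fell and none rose, and 39 passed adjusted over the list alone, with a median change of -0.76 (camera adjusted p = 1.01e-32; adjusted p = 0.0563 with an estimated correlation). Of 72 oxidative phosphorylation genes 20 fell and none rose, with 33 adjusted over the list alone and a median change of -0.66 (camera adjusted p = 1.73e-20; adjusted p = 0.0563 with an estimated correlation). UQCR11 of complex III fell at least 14.4-fold (7.85 ± 1.08 to 2.58 ± 0.56, adjusted p = 0.000367), NDUFB11 of complex I at least 10.1-fold (adjusted p = 0.000368) and COX4I1 of complex IV 6.33-fold (adjusted p = 0.000275).

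Of 33 translation factors 4 fell, EIF3G 8.37-fold among them (adjusted p = 0.000157), with 8 adjusted over the list alone (camera adjusted p = 0.0325; adjusted p = 0.487 with an estimated correlation, 0.23 with arrays centred on spike-in controls, 0.0784 with the mean of a gene's probe sets and 0.186 without 4 arrays that carried markers). Of 25 glycolysis genes 5 fell, ENO1 12.4-fold (adjusted p = 0.00506), with 6 adjusted over the list alone (camera adjusted p = 0.0325; adjusted p = 0.547 with an estimated correlation, 0.174 with fry and 0.515 without 4 arrays that carried markers). TKT fell 11.9-fold (adjusted p = 0.000157) and PTPMT1, a mitochondrial phosphatase of cardiolipin synthesis, at least 12.8-fold (adjusted p = 0.00039). Among the genes that rose were GLCE, an epimerase of heparan sulfate synthesis, by at least 7.57-fold (3.30 ± 0.93 to 7.01 ± 0.65, adjusted p = 0.000157), and PRKCH, a protein kinase C, by at least 5.56-fold (adjusted p = 3.49e-06). PANX1, a membrane channel, rose 6.26-fold (adjusted p = 0.0081) and CLDN1, a tight junction protein, 5.94-fold (adjusted p = 0.00611). None of 12 oocyte-specific genes passed.

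In this step 428 probe sets passed, 220 up and 208 down, in 224 genes of which 63 rose and 161 fell, and camera called 4 of 30 lists, all downward. The in vivo oocyte arrays are the ones used in the first comparison, so the falls from them are not independent of it, and the granulosa transcripts of in vivo oocyte array 2 apply here too. None of the genes in the cumulus (25), oviduct (10), blood (8) and sperm (5) lists passed, and the cumulus list had a camera adjusted p of 0.273. The count was 1128 without in vivo oocyte array 2 (370 up, 758 down), 226 without in vivo oocyte array 1 and 267 without zygote array 2. The balance of directions also moved without zygote array 1 (215 up, 120 down) and without zygote array 3 (121 up, 201 down). With a spread from the 6 arrays alone 0 passed (limma; 1270 at an unadjusted p under 0.05), and with arrays centred on spike-in controls 175 passed.

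From the zygote to the 2-cell stage single genes changed in both directions. HSD11B2, the enzyme that inactivates cortisol, fell 17.8-fold (10.17 ± 0.62 to 6.01 ± 0.51, adjusted p = 7.21e-06), and CTBP1, a transcriptional corepressor, fell 20.2-fold (adjusted p = 0.000348). THOC6, a member of the complex for mRNA export, fell at least 21.7-fold (adjusted p = 5.08e-05). TGFBR1, a receptor for TGF-beta, rose at least 5.38-fold (3.43 ± 1.25 to 6.72 ± 0.61, adjusted p = 0.000897) and LYN, a tyrosine kinase of the SRC family, at least 6.13-fold (adjusted p = 0.000367). Of 33 translation factors 7 rose and none fell, 14 passed adjusted over the list alone, and the median change was 0.63 (camera adjusted p = 0.00113; adjusted p = 0.436 with an estimated correlation). EIF4B, which aids the unwinding of mRNA, rose 2.91-fold (adjusted p = 0.00299, and 0.153 with arrays centred on spike-in controls). Ribosome biogenesis, with 1 of 29 genes up, and heat shock proteins, with 1 of 28 up and 1 down, were called upward, and primitive endoderm, with 2 of 16 down, was called downward. For these 3 lists the camera adjusted p was 0.00113, 0.00344 and 0.00344, and adjusted p = 0.499 with an estimated correlation for each. Counts adjusted over the list alone were 5, 11 and 3, and with fry, which tests each list by itself, all had an adjusted p of 0.0835.

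There were 467 probe sets past the test, 202 up and 265 down, in 237 genes. On 2-cell array 1 the secreted protein LTF stood at 13.86 (2.41 on 2-cell array 2), and it also carried AREG at 9.94, CST6 at 9.39 and S100A12 at 8.06. None of the cumulus, oviduct, blood and sperm genes passed in this step (camera adjusted p = 0.94 for the cumulus list). Zygote array 3 correlated at 0.971 and 0.972 with zygote arrays 1 and 2. Its correlations were higher with 2-cell array 2 (0.978) and 4-cell array 2 (0.979), and lower with 2-cell array 1 (0.963) and 4-cell array 1 (0.952). The count was 1180 without zygote array 3, and 134, 163, 248 and 172 without zygote array 1, zygote array 2, 2-cell array 1 and 2-cell array 2. Without 2-cell array 2 the larger part turned, with 115 up and 57 down. With a spread from the 5 arrays alone 0 passed (limma; 2814 at an unadjusted p under 0.05), and with arrays centred on spike-in controls 60 passed, 15 up and 45 down.

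From the 2-cell to the 4-cell stage 2 probe sets passed in limma, and 292 had an unadjusted p under 0.05. SUPT4H1, a transcription elongation factor, rose at least 4.58-fold (2.32 ± 0.35 to 6.20 ± 1.84, adjusted p = 0.0316). A probe set of ZFP36L1, a factor of mRNA decay named here after its values were seen, fell from 4.87 ± 0.43 to 3.16 ± 0.32 (adjusted p = 0.0316). None of 62 ribosomal protein genes passed, with none adjusted over the list alone, but their median change was -0.42 (camera adjusted p = 2.26e-24; adjusted p = 0.213 with an estimated correlation and 0.833 with fry). None of 72 oxidative phosphorylation genes passed either, with a median change of -0.32 (camera adjusted p = 1.64e-09; adjusted p = 0.357 with an estimated correlation and 0.954 with fry). The 4 lists of other cell types held no gene that passed. On 4-cell array 1, 9 of 14 leukocyte genes stood out, S100A12 at 13.05 and CD68 at 9.81 among them (4.72 and 1.97 on 4-cell array 2). CD14, CD68, LAPTM5, TYROBP, PTPRC and S100A9 lay above 4 on that array alone, so the filter left them out of all tests of the blood list. The count was 0 without 2-cell array 1 (308 at an unadjusted p under 0.05), 0 without 4-cell array 1 (211), 43 without 2-cell array 2 and 84 without 4-cell array 2. With a spread from the 4 arrays alone 0 passed (limma; 229 at an unadjusted p under 0.05).

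From the 4-cell to the 8-cell stage most oocyte-specific genes fell and most markers of embryonic genome activation rose. GDF9, a growth factor secreted by the oocyte, fell 83.8-fold (13.47 ± 0.01 to 7.08 ± 0.79, adjusted p = 7.23e-10), ZP2 of the zona pellucida fell 27.3-fold (adjusted p = 6.89e-10) and NLRP5, a maternal-effect gene, fell 23.5-fold (adjusted p = 3.28e-05). Of 12 oocyte-specific and maternal-effect genes 10 fell and 1 rose, 11 passed adjusted over the list alone, and the median change was -4.10 (camera adjusted p = 0.00457; adjusted p = 0.389 with an estimated correlation). The gene that rose was TRIM28, a corepressor that guards imprints, by 2.91-fold (adjusted p = 0.0041, and 0.0548 without 4-cell array 1). Of 17 markers of embryonic genome activation 11 rose, 1 fell and 5 did not pass, with 12 adjusted over the list alone and a median change of 1.52 (camera adjusted p = 0.0027; adjusted p = 0.0697 with an estimated correlation and 0.100 with the mean of a gene's probe sets). CHD1, a chromatin remodeller, rose at least 254.0-fold (2.75 ± 0.23 to 11.99 ± 0.09, adjusted p = 4.1e-15), NFYA, a promoter-binding factor, at least 237-fold (adjusted p = 3.7e-13) and MYC, a growth-promoting transcription factor, at least 91.6-fold (adjusted p = 1.93e-11), while RNF34, a ubiquitin ligase, fell 8.55-fold (adjusted p = 1.35e-06).

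Most genes of ribosomal proteins, ribosome biogenesis and translation rose in this step. Of 62 ribosomal protein genes 58 rose and 1 fell, 59 passed adjusted over the list alone, and the median change was 2.56 (camera adjusted p = 6.41e-16; adjusted p = 0.262 with an estimated correlation). RPS9 rose 44.4-fold (7.18 ± 0.71 to 12.66 ± 0.57, adjusted p = 4.96e-08) and RPL34 40.9-fold (adjusted p = 1.22e-09). Of 29 ribosome biogenesis genes 22 rose and 2 fell, with 24 adjusted over the list alone (camera adjusted p = 0.000135; adjusted p = 0.389 with an estimated correlation). NOP16, a nucleolar protein, rose at least 337-fold (adjusted p = 4.94e-10). Of 33 translation factors 22 rose and 3 fell, with 26 adjusted over the list alone (camera adjusted p = 0.000128; adjusted p = 0.13 with an estimated correlation). EIF3A rose at least 398-fold (adjusted p = 4.77e-08). Of 40 splicing genes 19 rose and 7 fell, with 26 adjusted over the list alone (camera adjusted p = 0.0181; adjusted p = 0.389 with an estimated correlation), and the splicing factor SRSF3 rose 29.6-fold (adjusted p = 4.91e-10). Of 72 oxidative phosphorylation genes 37 rose and 12 fell, with 51 adjusted over the list alone (camera adjusted p = 0.00375; adjusted p = 0.722 with an estimated correlation). UQCR10 rose 60.8-fold (adjusted p = 1.17e-10).

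Other lists moved in both directions without a call. Of 24 genes of oxidative stress defence 4 rose and 14 fell (camera adjusted p = 0.0585), of 18 transport genes 11 rose and 5 fell (0.0889), and of 17 genes for storage and decay of maternal mRNA 7 rose and 4 fell (0.843). By the size of the change the genes that rose included POLR1C, a subunit shared by RNA polymerases I and III, by at least 1081-fold (2.76 ± 0.31 to 14.08 ± 0.10, adjusted p = 2.56e-14), and AQP11, an aquaporin, by at least 265-fold (adjusted p = 5.83e-14). Those that fell included ME1, the cytosolic malic enzyme, by at least 170.4-fold (11.41 ± 0.57 to 2.68 ± 0.12, adjusted p = 3.33e-14), and BMPR1A, a receptor for bone morphogenetic proteins, by at least 114-fold (adjusted p = 3.39e-12).

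In this step 9236 probe sets passed (63.4%), 4340 up and 4896 down, in 4632 genes, and camera called 7 of 30 lists, 6 upward. Leukocyte transcripts on 4-cell array 1 bear on the blood list, in which 1 of 8 genes rose and 3 fell (camera adjusted p = 0.843). S100A8 fell by at least 9.00-fold with both 4-cell arrays (adjusted p = 0.00484), and its change was 0.000166 on the log2 scale (adjusted p = 1.00) without 4-cell array 1. The cumulus list had 4 up and 9 down of 25 (camera adjusted p = 0.735), the oviduct list 3 up and 3 down of 10 (0.82) and the sperm list 1 up and 2 down of 5 (0.82). The 8-cell arrays were not alike in maternal transcripts, since MOS, the kinase of meiotic arrest, stood at 6.46 and 6.59 on arrays 1 and 4 and at 10.65 and 10.70 on arrays 2 and 3.

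**Figure D3:**
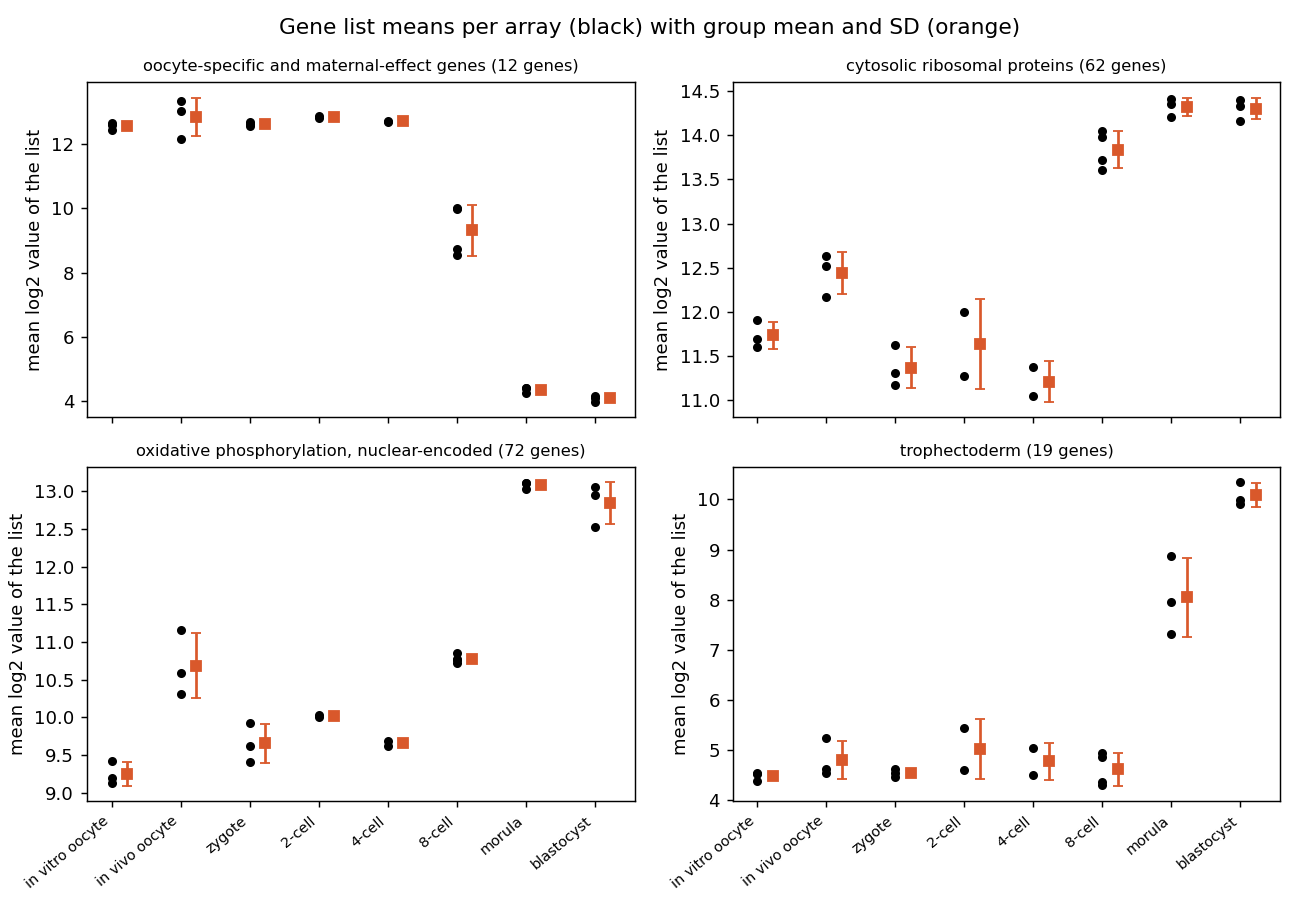
Each panel gives the mean log2 value of a gene list on every array (black points) with the mean and SD of each group (orange), for oocyte-specific genes (12), ribosomal proteins (62), oxidative phosphorylation (72) and trophectoderm (19). Oocyte-specific genes fall by medians of -4.10 from the 4-cell to the 8-cell stage and -5.64 from there to the morula, while ribosomal proteins rise by 2.56 at the former step and oxidative phosphorylation by 2.41 at the latter.

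From the 8-cell stage to the morula, most genes of the trophectoderm, the primitive endoderm, cell adhesion and oxidative phosphorylation rose. FN1, fibronectin, rose at least 696-fold (5.09 ± 1.44 to 14.66 ± 0.15, adjusted p = 7.54e-12) and PDPN, the membrane protein podoplanin, at least 699-fold (adjusted p = 2.67e-11). Of 19 trophectoderm genes 13 rose and 1 fell, with 14 adjusted over the list alone and a median change of 3.28 (camera adjusted p = 0.000874; adjusted p = 0.127 with an estimated correlation). PTGS2, a prostaglandin synthase, rose at least 60.3-fold (2.57 ± 0.53 to 9.91 ± 1.24, adjusted p = 1.16e-10), PAG2, a pregnancy-associated glycoprotein, at least 33.4-fold (adjusted p = 1.01e-06) and IFNT2, an interferon tau, at least 12.4-fold (adjusted p = 1.12e-06). Of 16 primitive endoderm genes 11 rose and none fell, with 11 adjusted over the list alone and a median change of 2.54, or 2.05 with low values at the limit of 4 (camera adjusted p = 0.00131; adjusted p = 0.155 with an estimated correlation). COL4A1 and LAMB1, chains of basement membrane collagen and laminin, rose at least 137-fold (adjusted p = 2.24e-12) and at least 56.7-fold (adjusted p = 6.8e-08).

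Genes of cell junctions changed in both directions, and those of energy metabolism mostly rose. Of 23 adhesion genes 14 rose and 3 fell, with 20 adjusted over the list alone and a median change of 1.37, or 1.17 with low values at the limit (camera adjusted p = 0.00478; adjusted p = 0.108 with an estimated correlation). The tight junction genes CLDN4 and CLDN10 rose at least 78.0-fold (adjusted p = 5.92e-11) and 72.6-fold (adjusted p = 3.95e-09), and the desmosomal gene DSC3 fell at least 26.0-fold (adjusted p = 1.52e-14). Of 72 oxidative phosphorylation genes 66 rose and 1 fell, with 67 adjusted over the list alone and a median change of 2.41 (camera adjusted p = 1.86e-14; adjusted p = 0.108 with an estimated correlation), and NDUFA3 of complex I rose 47.5-fold (6.21 ± 0.39 to 11.78 ± 0.21, adjusted p = 5.52e-11). Of 25 glycolysis genes 14 rose and 2 fell, with 16 adjusted over the list alone (camera adjusted p = 0.0065; adjusted p = 0.311 with an estimated correlation), GAPDH 21.1-fold (adjusted p = 3.08e-06). Of 24 genes of oxidative stress defence 12 rose and 3 fell, with 15 adjusted over the list alone (camera adjusted p = 0.0294; adjusted p = 0.311 with an estimated correlation). PRDX2, a peroxiredoxin, rose 27.3-fold (adjusted p = 3.96e-10). Of 62 ribosomal protein genes 25 rose and 1 fell, with 23 adjusted over the list alone (camera adjusted p = 0.00799; adjusted p = 0.612 with an estimated correlation, 0.0694 after quantile normalization and 0.0563 with arrays centred on spike-in controls).

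Most oocyte-specific genes, genes of meiosis and of maternal mRNA, and genome activation markers fell. Of 12 oocyte-specific genes 10 fell and none rose, with 10 adjusted over the list alone and a median change of -5.64, or -4.44 with low values at the limit (camera adjusted p = 7.41e-06; adjusted p = 0.108 with an estimated correlation). ZP2 fell at least 50.2-fold (9.65 ± 0.84 to 2.88 ± 0.16, adjusted p = 1.45e-12). Of 18 genes of meiosis 11 fell and 1 rose, with 12 adjusted over the list alone (camera adjusted p = 0.00498; adjusted p = 0.117 with an estimated correlation). STAG3, a meiotic cohesin, fell at least 63.8-fold (adjusted p = 4.3e-09). Of 17 genes for storage and decay of maternal mRNA 10 fell and 2 rose, with 12 adjusted over the list alone (camera adjusted p = 0.00498; adjusted p = 0.155 with an estimated correlation). TUT7, which marks mRNA for decay, fell 109-fold (14.38 ± 0.39 to 7.61 ± 0.46, adjusted p = 1.54e-10), and the deadenylase CNOT6L fell at least 18.6-fold (adjusted p = 7.54e-10). Of 17 genome activation markers 9 fell and 2 rose, with 11 adjusted over the list alone (camera adjusted p = 0.0167; adjusted p = 0.108 with an estimated correlation and 0.062 with the mean of a gene's probe sets). MYC fell at least 91.6-fold (10.52 ± 0.77 to 2.81 ± 0.37, adjusted p = 7.73e-12) and NFYA 18.0-fold (adjusted p = 2e-09).

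Of 29 ribosome biogenesis genes 16 fell and none rose, with 16 adjusted over the list alone (camera adjusted p = 0.00325; adjusted p = 0.367 with an estimated correlation). DDX21, a nucleolar helicase, fell 13.0-fold (adjusted p = 3.96e-09). Of 32 genes of RNA polymerase II and general transcription factors 18 fell and 3 rose, with 21 adjusted over the list alone (camera adjusted p = 0.00498; adjusted p = 0.311 with an estimated correlation). POLR2A, its largest subunit, fell 5.16-fold (adjusted p = 8.16e-06). Of 35 mitotic genes 16 fell and 3 rose, with 19 adjusted over the list alone (camera adjusted p = 0.0255; adjusted p = 0.231 with an estimated correlation), with CDK1 down 6.27-fold (adjusted p = 0.000499) and CCND2, a cyclin of the G1 phase, up at least 54.8-fold (adjusted p = 1.52e-05). In all 8090 probe sets passed (55.5%), 3934 up and 4156 down, in 4132 genes, and camera called 14 of 30 lists, 7 in each direction. Donor set, collection site and day also differ between these stages and cannot be told apart from stage. Of the lists of other cell types, cumulus markers had 9 up and 5 down of 25 (camera adjusted p = 0.396), oviduct markers 2 up and 4 down of 10 (0.628), blood markers 3 up of 8 (0.178) and sperm transcripts 1 down of 5 (0.628). KRT18, a keratin of epithelia, rose at least 413-fold (5.38 ± 3.61 to 14.94 ± 0.25, adjusted p = 2.55e-05), but it stood at 8.61 and 8.40 on 8-cell arrays 1 and 4 against 2.38 and 2.15 on arrays 2 and 3.

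From the morula to the blastocyst, 9 of 19 trophectoderm genes and 6 of 24 genes of cholesterol and fatty acid synthesis rose. TKDP1, a trophoblast protease inhibitor, rose at least 25.8-fold (4.75 ± 2.02 to 9.80 ± 0.29, adjusted p = 8.67e-06), TFAP2A, a transcription factor of trophoblast, from 4.15 ± 2.15 to 8.90 ± 1.08 (adjusted p = 8.46e-05) and SSLP1 22.5-fold (adjusted p = 1.19e-06). Of 19 trophectoderm genes 9 rose, none fell and 10 did not pass, with 10 adjusted over the list alone and a median change of 1.77, or 1.57 with low values at the limit (camera adjusted p = 1.53e-07; adjusted p = 0.0643 with an estimated correlation). Of 24 genes of cholesterol and fatty acid synthesis 6 rose and 1 fell, with 9 adjusted over the list alone and a median change of 0.82 (camera adjusted p = 4.49e-05; adjusted p = 0.139 with an estimated correlation). CYP51A1, lanosterol demethylase, rose 15.2-fold (7.23 ± 1.06 to 11.16 ± 0.73, adjusted p = 7.68e-06) and HMGCS1, HMG-CoA synthase, 4.47-fold (adjusted p = 1.4e-05), while ELOVL6, a fatty acid elongase, fell 4.06-fold (adjusted p = 0.00114).

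At the same step STAR, which carries cholesterol into mitochondria, rose 7.88-fold (7.19 ± 1.61 to 10.17 ± 0.17, adjusted p = 0.000534) and HSD3B1, a steroid dehydrogenase, 43.1-fold (adjusted p = 0.000441). Both stand in the list of cumulus and granulosa markers, of which 6 of 25 rose and none fell, with 7 adjusted over the list alone and a median change of 0.65, or 0.33 with low values at the limit (camera adjusted p = 0.00261; adjusted p = 0.349 with an estimated correlation). Of those 6, 3 (PTGS2, KRT8 and CYP11A1) also stand in the trophectoderm list. KRT8 (adjusted p = 0.0282) did not pass without morula array 2 (0.182), morula array 3 (0.106), blastocyst array 1 (0.202) or blastocyst array 2 (0.0572), nor with arrays centred on spike-in controls (0.0514). CYP11A1 (adjusted p = 0.00888) did not pass without morula array 2 (0.0602). Of 35 mitotic genes 4 fell, with 6 adjusted over the list alone (camera adjusted p = 0.00865; adjusted p = 0.269 with an estimated correlation), among them CCNB1, cyclin B1, 2.09-fold (adjusted p = 0.00046). Another, CDC20 (adjusted p = 0.013), did not pass with arrays centred on spike-in controls (0.121) or without morula array 2 (0.0846) or blastocyst array 1 (0.0749). RNA polymerase II genes were called downward with 1 of 32 fallen and 1 adjusted over the list alone (camera adjusted p = 0.000297; adjusted p = 0.312 with an estimated correlation). That gene, TAF2 (adjusted p = 0.0134), did not pass with arrays centred on spike-in controls (0.161), without morula array 2 (0.103) or without blastocyst array 1 (0.0984). Calls for meiosis (2 of 18 fell, camera adjusted p = 0.0477; 0.312 with an estimated correlation) and proteasome (0 of 26 passed, camera adjusted p = 0.0454; 0.47 with an estimated correlation) ended after quantile normalization (0.0613 and 0.228), with arrays centred on spike-in controls (0.0779 and 0.0671) and without 4 arrays that carried markers (0.0823 and 0.117). The proteasome call also ended with fry (0.093).

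Other genes that rose included UPP1, uridine phosphorylase, by at least 38.6-fold (adjusted p = 1.4e-05). SLC9A3, a sodium-proton exchanger of the transport list, rose at least 30.9-fold (3.29 ± 0.98 to 9.09 ± 0.26, adjusted p = 7.8e-08). EPAS1, a hypoxia-inducible factor, rose at least 30.4-fold (adjusted p = 0.000373) and CRIPTO, a co-receptor of NODAL, 45.2-fold (adjusted p = 2.97e-08). The cytokine IL6 fell at least 20.1-fold (9.85 ± 0.99 to 5.15 ± 2.01, adjusted p = 0.000278) and CD36, a fatty acid transporter, at least 10.8-fold (adjusted p = 0.00157). In all 1305 probe sets passed, 771 up and 534 down, in 672 genes, and camera called 7 of 30 lists, 3 upward. No ribosomal or oxidative phosphorylation gene passed in this step. Blastocyst array 1 carried LTF at 13.18, against 3.14 and 2.42 on the other blastocyst arrays. The oviduct list had 1 of 10 up (MUC1, at least 5.28-fold, adjusted p = 0.000151; camera adjusted p = 0.303 for the list), the blood list 2 of 8 down (0.166) and the sperm list 1 of 5 up (0.245). Morula array 1 correlated at 0.9722 and 0.9675 with morula arrays 2 and 3, and at 0.9708 with blastocyst array 2. The count was 1390 without morula array 1, 749 without morula array 2, 836 without morula array 3, 776 without blastocyst array 1 and 753 without 4 arrays that carried markers. With a spread from the 6 arrays alone 534 passed, and with arrays centred on spike-in controls 638.

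From the in vivo oocyte to the blastocyst most oocyte-specific genes fell and most trophectoderm genes rose. KPNA7, an importin of the oocyte, fell at least 3461-fold (15.76 ± 0.04 to 2.35 ± 0.11, adjusted p = 2.47e-12), ZP2 at least 1445-fold (adjusted p = 6.6e-16) and MOS at least 714.0-fold (adjusted p = 1.44e-10). PLAC8A, an early placental marker of cattle, rose at least 1040.3-fold (2.28 ± 0.01 to 14.02 ± 0.28, adjusted p = 6.99e-17) and SLC2A5, a fructose transporter, at least 1015-fold (adjusted p = 1.54e-14). Of 12 oocyte-specific genes 10 fell and none rose, with 10 adjusted over the list alone and a median change of -10.04, or -8.62 with low values at the limit (camera adjusted p = 7.13e-07; adjusted p = 0.0851 with an estimated correlation). Of 18 meiosis genes 14 fell, with 14 adjusted over the list alone (camera adjusted p = 0.000718; adjusted p = 0.0851 with an estimated correlation). AURKA, an aurora kinase, fell 14.4-fold (adjusted p = 1.6e-11).

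Of 19 trophectoderm genes 18 rose, with 18 adjusted over the list alone and a median change of 6.04, or 4.50 with low values at the limit (camera adjusted p = 3.85e-05; adjusted p = 0.0851 with an estimated correlation). DAB2, an endocytic adaptor, rose 164-fold (adjusted p = 2.26e-07) and PAG2 at least 318-fold (adjusted p = 7.12e-09). Of 62 ribosomal protein genes 58 rose, with 58 adjusted over the list alone (median change 1.87, camera adjusted p = 4.86e-10; adjusted p = 0.231 with an estimated correlation), and of 72 oxidative phosphorylation genes 60 rose, with 62 adjusted over the list alone (median change 2.15, camera adjusted p = 7.21e-09; adjusted p = 0.179 with an estimated correlation). Of 23 adhesion genes 14 rose and 4 fell, with 18 adjusted over the list alone (camera adjusted p = 0.0122; adjusted p = 0.0851 with an estimated correlation). CLDN4 rose at least 212-fold (adjusted p = 2.42e-12). Of 18 transport genes 11 rose and 4 fell, with 15 adjusted over the list alone (camera adjusted p = 0.0411; adjusted p = 0.148 with an estimated correlation and 0.0504 with the mean of a gene's probe sets). AQP3, a water and glycerol channel, rose 89.5-fold (6.12 ± 0.98 to 12.60 ± 0.72, adjusted p = 8.41e-08). CA2, a carbonic anhydrase, fell 97.9-fold (adjusted p = 1.12e-10). Of 33 translation factors 24 rose and 5 fell, with 29 adjusted over the list alone (camera adjusted p = 0.0011; adjusted p = 0.146 with an estimated correlation). In all 9420 probe sets passed, 4695 up and 4725 down, in 4871 genes, and camera called 13 of 30 lists, 9 upward. The remaining 5, upward for ribosome biogenesis, heat shock proteins and proteasome and downward for RNA polymerase II and mitotic genes, had camera adjusted p values from 0.0319 to 0.0411 and adjusted p values from 0.264 to 0.486 with an estimated correlation. Each of these 5 calls ended with arrays centred on spike-in controls or without 4 arrays that carried markers. The lists of other cell types gave no call here, with 12 up and 4 down of 25 cumulus markers, 2 up and 5 down of 10 oviduct markers, 2 up and 1 down of 8 blood markers and 2 up and 3 down of 5 sperm transcripts.

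Over the 7 in vivo stages 12822 of 14571 probe sets (88.0%) passed the F test, and 12738 of these spanned at least 1 on the log2 scale between stage means. When each was assigned to the step with its largest change, 3323 (26.1%) rose and 3731 (29.3%) fell most from the 4-cell to the 8-cell stage, 2332 rose and 1815 fell most from the 8-cell stage to the morula, and 466 rose and 217 fell most from the morula to the blastocyst. The earlier steps held 103 up and 111 down (oocyte to zygote), 224 up and 361 down (zygote to 2-cell) and 10 up and 45 down (2-cell to 4-cell). At the 8-cell stage 2172 probe sets reached their highest level and exceeded both the oocyte and the blastocyst by at least 1 (adjusted p under 0.05 for both), against 490 at the 4-cell stage, 349 at the 2-cell stage, 165 in the morula and 28 in the zygote. By a count made after these were seen, every array of the stage exceeded both means by at least 1 for 1405 (8-cell), 453 (4-cell), 320 (2-cell), 112 (morula) and 18 (zygote) of them. Among the 10 named genes furthest above both at the 4-cell stage, 5 (S100A12, DEFB4A, CXCL2, CTSS and BCL2A1) had SDs of 5.68 to 6.85 between the 4-cell arrays, of which array 1 carried leukocyte transcripts. GRO1, a chemokine, went from 2.73 in the oocyte to 13.04 ± 1.01 at the 8-cell stage and 3.69 in the blastocyst, and GUCY2C, a guanylate cyclase receptor, from 2.26 to 10.07 ± 0.53 and 2.21. IL6 was highest in the morula, at 9.85 ± 0.99, against 2.51 in the oocyte and 5.15 in the blastocyst, and GLCE was highest at the 4-cell stage, at 9.40 ± 0.33.

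**Figure D4:**
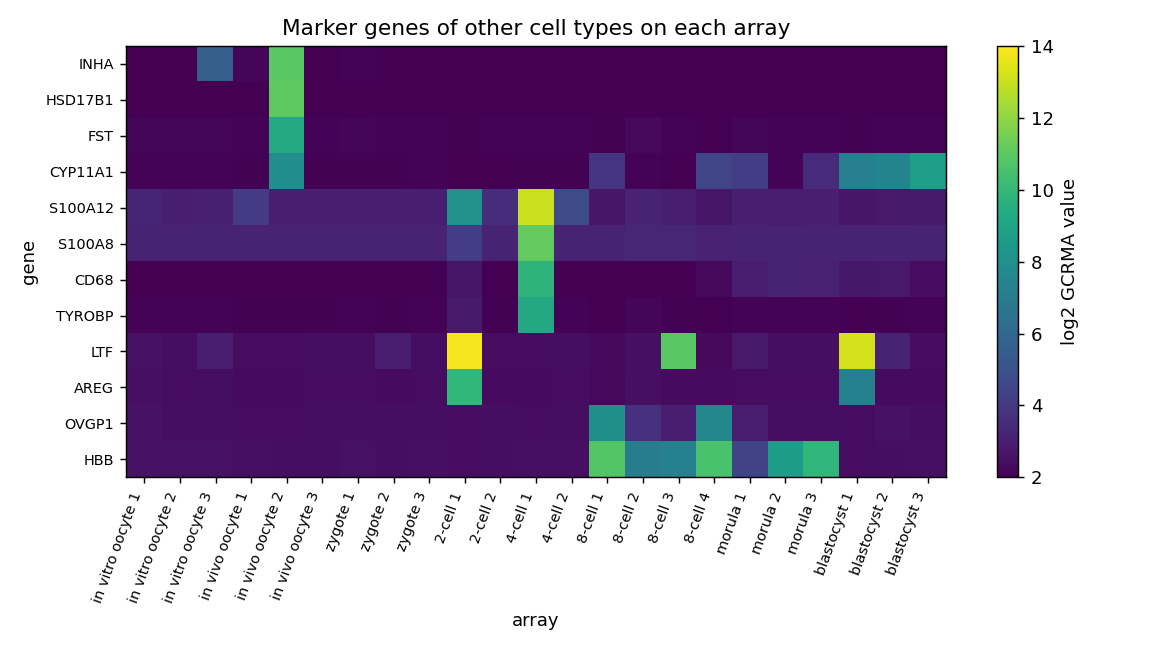
Colour gives the log2 value of 12 marker genes of other cell types (lines) on each of the 23 arrays (columns). INHA and HSD17B1 stand out on in vivo oocyte array 2 (10.95 and 11.03), S100A12 and CD68 on 4-cell array 1 (13.05 and 9.81), and LTF on 2-cell array 1 and blastocyst array 1 (13.86 and 13.18).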

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

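The tests of granulosa RNA, maturation, leukocyte RNA, progress of the 8-cell embryos and dilution were chosen after their results were seen, and the counts over other splits of the arrays were planned.

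Among 72 results examined over the 4 arrays of the 8-cell group, 4 had an array far from the others, no more than about what the chance of 1 in 20 gives. The gap of that array to its nearest neighbour, as a share of the whole range, was 0.916 for ANXA8L1 (2.32 on array 1, 1.93 to 1.96 on the others), 0.851 for FBXO34 (4.35 on array 3, 2.55 to 2.82 on the others), all but 1 of these values under 4 and so not told from background, and 0.875 for GSTM3 (11.61 on array 1, 11.98 to 12.04 on the others). It was 0.986 for the mean of the oxidative stress list (8.94 on array 3, 8.50 to 8.51 on the others).

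Other splits of the same arrays into groups of the same sizes were counted for each comparison with at least 3 arrays per group. From the 8-cell stage to the morula 1 of 35 splits, the real one, gave as many calls (8090, highest other 5699). For the F test 1 of 100 splits did, again the real one (12822, highest other 5187). These are the smallest shares that such counts can reach, so chance is an unlikely source of either count but is not excluded. The split with 5699 calls set 8-cell array 1 with the morulae against the other 8-cell arrays. With 3 arrays against 3 there are 10 splits, too few for a share under 0.05. There the real split gave 1245 calls for in vitro against in vivo oocytes (highest other 138), 1305 from the morula to the blastocyst (highest other 57) and 9420 from the oocyte to the blastocyst (highest other 6), each the 1 split with as many. From the oocyte to the zygote 2 of 10 splits gave as many as the real one, 428. The other, with 836 calls, set in vivo oocyte arrays 1 and 3 with zygote array 3 against in vivo oocyte array 2 with zygote arrays 1 and 2, which points to a structure of the samples apart from their groups. By the array correlations in vivo oocyte array 2 was nearer to the in vitro oocytes than to its own group. Zygote array 3 was nearer to 2-cell array 2 and 4-cell array 2 (0.978 and 0.979) than to zygote arrays 1 and 2 (0.971 and 0.972). What sets these arrays apart was not tested.

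Most probe sets called between in vitro and in vivo oocytes were lower in vitro (1048 of 1245). RNA of granulosa cells on in vivo oocyte array 2 is argued against as the source, because over these probe sets that array exceeded the in vitro mean by a median of 0.989, against 3.09 and 2.20 on in vivo oocyte arrays 1 and 3. On in vivo oocyte array 1, 2 of 22 blood and leukocyte genes stood out, CD52 at 8.47 (5.66 and 5.71 on arrays 2 and 3) and CD3E at 5.13. PTPRC (3.115), LAPTM5 (2.366) and TYROBP (2.073) stayed low there. RNA of other cells on that array was not tested as a source. A candidate explanation is that the in vivo oocytes were at an earlier point of maturation, since the in vitro change and the zygote change, computed with no shared array, had a Pearson r of 0.514 and 0.673 across 7074 genes, which are not independent replicates. Anything else that sets in vivo oocyte arrays 1 and 3 apart, such as RNA quality or yield, would give the same correlation. The culture itself, the difference that the labels name, stays open and was not tested apart from these.

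Leukocyte transcripts stood out on 4-cell array 1. Of 14 leukocyte genes in the fixed list of blood markers, 9 lay above 4 and over 2 (log2) above each of the other 2-cell and 4-cell arrays, as leukocyte RNA in that pool would give. S100A12 stood at 13.05, S100A8 at 11.14, CD68 at 9.81, LAPTM5 at 9.70, TYROBP at 9.25 and CD14 at 8.26, while the T- and B-cell genes CD3E (2.92) and CD79A (2.34) stayed low and CD52 was alike on both 4-cell arrays (5.36 and 5.49). The labels name no sorting of cells, only washing of the embryos, so a candidate explanation is myeloid cells carried over in flushing. The design gives no biological explanation for a single array, and none was tested.

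The 8-cell arrays differed in maternal transcripts, with BMP15 at 6.94, 10.88, 11.32 and 7.55, MOS at 6.46, 10.65, 10.70 and 6.59 and KPNA7 at 9.93, 13.19, 13.43 and 9.61 on arrays 1 to 4, and the opposite order for KRT18 (8.61, 2.38, 2.15, 8.40) and OVGP1 (7.96, 3.63, 3.01, 7.62). OVGP1 is in the list of oviduct markers, and other markers of cells outside the embryo differed by array as well, some in the same order: HOXA10 (5.84, 2.83, 2.68, 6.88), LUM (6.28, 2.95, 2.78, 7.46) and DCN (3.81, 2.22, 2.15, 4.85), and some like the maternal transcripts: ADAMTS1 (5.80, 9.71, 9.40, 6.71), CFTR (11.88, 13.31, 13.60, 12.23) and SPP1 (4.22, 6.08, 5.76, 2.33). GAPDH 3′ minus 5′, a sign of RNA quality, was 3.80, 3.46, 2.53 and 4.14. Dilution by RNA of other cells on arrays 1 and 4 was examined as a source of the maternal difference. The 2172 probe sets highest at the 8-cell stage had medians of 9.40, 9.30, 9.44 and 9.40. The lower of arrays 1 and 4 thus lay -0.0409 from the higher of arrays 2 and 3. For the median of 12 maternal genes even the higher of arrays 1 and 4 lay -1.18 from the lower of arrays 2 and 3. A first bound for that test asked for a maternal fall of more than 2, which the median did not reach, and it was replaced after the value was seen. The 2172 probe sets were also chosen by the mean of these same 4 arrays, on values quantile normalized across arrays. So the test does not decide whether dilution was a source. Embryos further along on arrays 1 and 4 are a candidate explanation, since over 3332 probe sets that rise from the 4-cell stage to the morula the arrays had covered a median of 73.9%, 52.8%, 55.8% and 73.3% of the rise, a difference of 17.5 between the nearest of them. The series text describes the stage as 8 to 16 cells but gives no cell number per array, so this stays a hypothesis. It was not tested against RNA quality, nor against RNA of other cells as the source of the markers on arrays 1 and 4, and no other biological explanation was tested.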

How the results depend on the processing

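The alternatives without 4 or 6 arrays that carried markers of other cell types were chosen after the data were seen, and the others were planned. Counts within 1.5 times those reported, for all comparisons, came from eBayes without a trend and the 2-fold threshold. Where a count left that range the cause was not tested, except for genes in place of probe sets, where fewer tests were made. From the 2-cell to the 4-cell stage the count of 2 became 21 with no filter, 1 with the stricter filter, 1 after quantile normalization and 1 over genes. It was 0 with spike-in centring (434 at an unadjusted p under 0.05), median centring (237), robust eBayes (288), the replicate block (308), the compared groups alone (229) and without 4 (199) or 6 (190) arrays that carried markers. With spike-in centring limma called 686 (in vitro against in vivo oocytes), 175 (oocyte to zygote), 60 (zygote to 2-cell) and 638 (morula to blastocyst). With the compared groups alone it called 4, 0, 0 and 534 (3051, 1270 and 2814 at an unadjusted p under 0.05 for the first 3). Over genes the counts were 234, 244, 4644, 4156, 685 and 4893 for oocyte to zygote, zygote to 2-cell, 4-cell to 8-cell, 8-cell to morula, morula to blastocyst and oocyte to blastocyst, and 6412 for the F test. Without 4 arrays that carried markers they were 2377 for in vitro against in vivo oocytes, 1058 for oocyte to zygote and 753 for morula to blastocyst, and within 1.5 times at 349 (zygote to 2-cell), 8063 (4-cell to 8-cell), 8189 (8-cell to morula), 8509 (oocyte to blastocyst) and 12376 (F test). Without 6 such arrays they were 2066 for in vitro against in vivo oocytes, 1066 for oocyte to zygote, 277 for zygote to 2-cell and 700 for morula to blastocyst, and within 1.5 times for the others. Both fits kept 8-cell arrays 1 and 4, which carried OVGP1, HOXA10 and LUM. For the steps to and from the 8-cell stage they do not show how far RNA of other cells on those arrays bears on the counts. With stage means at least 2 apart, classes of largest change held 67 (oocyte to zygote, up), 143 and 230 (zygote to 2-cell, up and down), 28 (2-cell to 4-cell, down) and 140 (morula to blastocyst, down).

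Leaving out each array in turn gave 508 (without in vivo oocyte 1) to 2439 (without in vivo oocyte 2) for in vitro against in vivo oocytes, 226 to 1128 (the same arrays) for oocyte to zygote, 134 (without zygote 1) to 1180 (without zygote 3) for zygote to 2-cell, 0 (without 2-cell 1, 308 at an unadjusted p under 0.05) to 84 (without 4-cell 2) for 2-cell to 4-cell and 749 (without morula 2) to 1390 (without morula 1) for morula to blastocyst. The ranges were 7849 to 9276 for 4-cell to 8-cell, 7158 to 7969 for 8-cell to morula, 8813 to 9227 for oocyte to blastocyst and 12594 to 12947 for the F test. Of 60 list calls, 55 passed after quantile normalization, 52 with spike-in centring, 60 with the replicate block, 54 with the mean of a gene's probe sets, 53 with fry, 52 without 4 arrays that carried markers and 0 with an estimated correlation, and none reversed. Of 258 gene results, 255 passed after quantile normalization, 254 with the block, 254 without a trend, 232 with spike-in centring and 236 without 4 arrays that carried markers, and 40 lost their call without at least 1 array. For a single gene, S100A8 from the 4-cell to the 8-cell stage, the sign turned as the change vanished, to 0.000166 (adjusted p = 1.00) without 4-cell array 1 and without the 4 arrays that carried markers. Without 4-cell array 2 its change was -7.93. Scaling moved the median change of all probe sets by over 0.1 with spike-in centring (-0.44 for 2-cell to 4-cell, -0.36 for oocyte to blastocyst, 0.11 for oocyte to zygote) and median centring (0.22 for in vitro against in vivo oocytes, 0.18 for 4-cell to 8-cell, -0.16 for zygote to 2-cell, -0.11 for 8-cell to morula). The share that rose was then 30.9% in place of 15.8% (in vitro against in vivo oocytes, median centring; 6.41% with spike-in centring) and 23.5% in place of 43.3% (zygote to 2-cell, median centring; 15 of 60 with spike-in centring). Signal over background limits folds, which are bounds where an array of the lower group is below a log2 value of 4.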

Other observations

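Genes of DNA methylation took separate courses, and no list test called them (camera adjusted p = 0.735 from the 4-cell to the 8-cell stage and 0.628 from there to the morula, where the median change of -0.72 and the mean of 0.13 differ in sign). DNMT1, the maintenance methyltransferase, fell 11.3-fold from the 4-cell to the 8-cell stage (11.91 ± 0.37 to 8.41 ± 0.40, n = 2 and 4, limma adjusted p = 8.34e-08), and UHRF1, its partner at replicating DNA, fell 17.9-fold at that step (adjusted p = 8.25e-08) and at least 34.2-fold at the next (adjusted p = 8.46e-11). DNMT3A, a de novo methyltransferase, fell at least 6.97-fold to the 8-cell stage (adjusted p = 0.000839) and rose at least 195-fold to the morula (4.48 ± 1.60 to 12.46 ± 0.37, adjusted p = 3.49e-09). TDG, a glycosylase of active demethylation, rose at least 30.5-fold from the 8-cell stage to the morula (adjusted p = 1.24e-12). Of 11 measured genes 3 rose and 5 fell from the 4-cell to the 8-cell stage and 2 rose and 5 fell to the morula, 8 and 9 of them past the test adjusted over the list alone. Of 31 histone and chromatin enzymes 11 rose and 9 fell to the 8-cell stage (camera adjusted p = 0.61), and of 19 apoptosis genes 10 rose and 2 fell to the morula (camera adjusted p = 0.219).

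Imprinted genes also went both ways. Of 16 measured, 6 rose and 5 fell to the 8-cell stage (camera adjusted p = 0.805), with NDN up at least 152-fold (adjusted p = 8.23e-10) and MEST down 20.7-fold (adjusted p = 2.32e-07). PHLDA2 fell 64.7-fold from there to the morula (14.07 ± 0.78 to 8.06 ± 0.48, adjusted p = 6.17e-08), and MEG3 rose at least 5.46-fold to the blastocyst (adjusted p = 2.21e-05). Of 13 interferon-response genes 5 rose and 1 fell from the 8-cell stage to the morula (camera adjusted p = 0.27), with IFI35 up at least 37.6-fold (adjusted p = 2.79e-10) and IFITM1 at least 8.96-fold (adjusted p = 1.46e-05). POU5F1, the pluripotency factor OCT4, rose 22.2-fold at that step (8.75 ± 1.13 to 13.22 ± 0.16, adjusted p = 4.55e-08), where 5 of 9 pluripotency genes rose and 1 fell (camera adjusted p = 0.254).

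Some probe sets of beta-like globins gave signal in 8-cell embryos and morulae. A probe set of HBB stood at 10.79, 7.07, 7.29 and 10.54 on 8-cell arrays 1 to 4, at 4.45, 8.62 and 9.89 on the morula arrays and between 2.41 and 2.49 on the blastocyst arrays, and another of HBB (6.48 to 11.27 on the 8-cell arrays) had a like course. The 2 other HBB probe sets stayed between 2.06 and 3.16 on all arrays, and HBA between 2.27 and 2.65. The first HBB probe set rose at least 30.3-fold from the 4-cell to the 8-cell stage (adjusted p = 3.11e-05) and fell at least 12.6-fold from the morula to the blastocyst (adjusted p = 0.00226). ALAS2, an enzyme of heme synthesis in red cells, stood at 7.84, 5.53 and 3.66 on the morula arrays and at 6.28 on blastocyst array 2, where the globins were below 3. LTF, apart from 2-cell array 1 and blastocyst array 1, was also high on 8-cell array 3, at 10.94.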
